A study of Triticum aestivum with 24 samples.

How the data were processed

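Total RNA from the feeding site of Hessian fly larvae, a piece of the second leaf sheath, was hybridised to 24 Affymetrix wheat arrays, 3 for each of 8 groups. The groups were Molly and Newton sheaths at 6, 12 and 24 h after egg hatch and uninfested sheaths of each line at 12 h. The deposited values are intensity per probe set on a linear scale, made by the authors with MAS5 per the labels; the MAS5 version and settings are not given in the sources used here. The trimmed mean of the signal, between the percentiles 2 and 98, was 500 on every array, so the authors' scaling to 1 target was kept. No pair of arrays held identical values.

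Of 61290 probe sets, 111 controls were set aside and 61179 wheat probe sets were kept. The 40% with the lowest mean log2 signal over all arrays were left out (mean signal 44.8 at that limit), which left 36707 tested probe sets with a median mean signal of 308. The array's 8 tag controls, which match no wheat transcript, had a median signal of 18.9 and reached 85 on 1 array, so signals in that range are not told from background. Where 1 group of a named probe set had a geometric mean in that range, its change is given as at least the ratio of the brighter group to 85, a rule added after seeing the data. Fitted changes are also printed for some results, such as those not called and those of alternative settings. The number of arrays limits the precision, since the deposited values hold no counts.

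Log2 signal was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and a variance prior that followed intensity (16 residual and 4.49 prior degrees of freedom). Each infested group was compared with the uninfested group of its line, the responses of Molly and Newton were compared at each time as a difference of differences, and the uninfested lines were compared with each other. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p; "rose", "fell" and "changed" are used of results past it. The 3 uninfested arrays of a line serve all 3 of its time points, so those comparisons are not independent of each other. The labels call the infested replicates biological and only number the uninfested ones, and nothing used here says that the latter came from separate plants, so p-values against them measure only the spread between these arrays, which may be technical. Since uninfested sheaths were taken at 12 h alone, the comparisons at 6 and 24 h hold plant age and time of day as well as infestation.

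The supplied array annotation paired 1273 probe sets with 1 gene, 771 genes in all, of which 770 were in the supplied RefSeq table, and 59906 probe sets with none. Of these genes, 100 had a symbol or title that says what they are; 76 of them, with 132 probe sets, were tested. The names printed for them were shortened after their values had been seen. For each infested group the rule for naming took up to 6 genes that rose and 6 that fell by the largest log2 change, among those whose 3 infested arrays all lay on one side of the 3 uninfested arrays (10% of probe sets do so by chance) and whose brighter group exceeded the median signal. For differences between lines and for the uninfested lines it took up to 3 in each direction, the no-overlap condition being dropped for differences. Each gene list added up to 2 members past the threshold and 1 that was not. A gene whose call rested on 1 array is named with that array, or left to the counts. Genomic positions were not used here.

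Before the data were examined, 22 gene lists by title were fixed along with the groups, tests and naming rule; 0 of them reached 5 tested probe sets, so none was tested. A further 13 lists by symbol were written after the annotation had been read and before any expression value was compared between groups, and 10 reached 5 tested probe sets. Those were inhibitors of digestive enzymes with serpins; peroxidases and detoxification; methyl donor cycle and phenolic methylation; cell wall, lipid transfer and glucosidase genes; photosynthesis and the Calvin cycle (also a marker of green tissue); starch, fructan and sugar metabolism; histones and chromatin (also a marker of dividing cells); tubulins and profilin; translation; and LEA, dehydrin and heat shock genes. Lists of thionins, PR5 and wheat germ agglutinin, of gibberellin 20-oxidases, and of seed storage and anther genes were too small and are given by their tested members. The last was meant as a marker of background in leaf sheath, but its member ALP had a mean signal of 4410 and so does not mark background. The thionins and PR5 were below the filter and were not tested. Lists were tested against all other probe sets with camera, at a preset correlation of 0.01 between probe sets and again with the correlation estimated from the arrays, adjusted over 10 lists in 10 comparisons.

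RNA quality was read from control probe sets for wheat 18S rRNA and from log2 ratios of 3' to 5' probe sets, compared between infested and uninfested arrays within lines by a two-sided exact permutation test over 48400 splits, with adjustment over the 5 measures. Changes of single wheat control probe sets were fitted in limma along with the tested ones. Their p-values were adjusted over these controls alone, in all infested groups together. The pipeline was tested on simulated data with the real spread. In the comparison of Molly at 6 h, 18% of 50 probe sets simulated with a log2 change of 0.5 were recovered. The shares were 60% at 1, 90% at 2 and 54% at -1, with 8 false calls among the unchanged of 36707 simulated probe sets. For the difference between lines at 6 h the shares were 6%, 34%, 70% and 30%, with 4 false calls. Far fewer probe sets were changed in the simulation than the 37.7% called in Molly at 6 h. The adjusted threshold was therefore stricter there, and the shares may be lower than in the real data.

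The alternatives were quantile normalization, arrays centred on their median, no filter, the lowest 60% left out, a pseudocount of 14.4 (percentile 20 of the values), a variance prior without the intensity trend, only the arrays of the compared groups, the replicate number as a block, a change of at least 2-fold, and each replicate left out in turn. A fit with log2 18S rRNA signal as a covariate was added after seeing the data.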

Results

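Gene expression was measured at the site where Hessian fly larvae feed on wheat seedlings. Molly carries the resistance gene H13 and its interaction with the larvae is incompatible, while Newton is susceptible and its interaction is compatible. Each line was sampled at 6, 12 and 24 h after egg hatch and, without larvae, at 12 h, with 3 arrays in each of 8 groups and 24 arrays in all. Summed signal per array ranged from 45362600 to 47970500 units and median signal from 78.6 to 101. Log2 signal correlated at r = 0.951 to 0.974 between arrays of one group and 0.878 to 0.966 between arrays of different groups. The first principal component, with 34.5% of the variance, placed infested Molly arrays between 29.0 and 100.5 and every other array below 0. The second, with 16.1%, placed the uninfested arrays of both lines between -45.8 and -60.7 and the infested Newton arrays between 2.1 and 79.2. Some arrays stood apart from their group on the first component: Newton 6 h replicate 3 lay at -12.9, against -50.4 and -52.0 for the other replicates, and Molly 24 h arrays spread from 29.0 to 84.5.

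**Figure D1:**
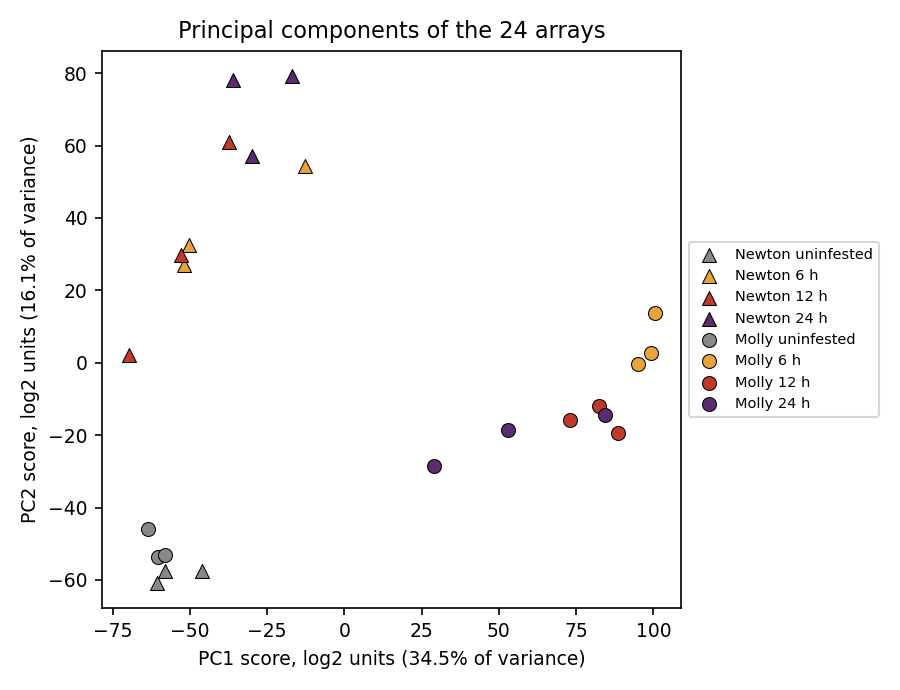
Principal components of log2 signal over 36707 tested probe sets, with 1 point per array and the share of variance on each axis (PC1 34.5%, PC2 16.1%). Infested Molly arrays lie at 29.0 or above on PC1, and uninfested arrays of both lines lie at -45.8 or below on PC2.

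The 18S rRNA control and some of the RNA quality ratios also differed between infested and uninfested arrays. The wheat 18S rRNA control probe set was lower on infested arrays, by a mean over the lines of -1.65 on the log2 scale (18 infested and 6 uninfested arrays, exact permutation p = 4.1e-05, BH-adjusted p = 2e-04). Its signal was 5270 ± 1400 in uninfested Molly and 1530 to 2800 in infested Molly, and 6580 ± 1800 in uninfested Newton and 1550 to 2440 in infested Newton (mean ± SD, n = 3). The log2 ratio of 3' to 5' signal differed by -0.53 for sucrose synthase (exact permutation p = 0.008, BH-adjusted p = 0.013) and by -0.54 for CYP86 (exact permutation p = 0.0025, BH-adjusted p = 0.0062). These are means over the lines, of -0.32 in Molly and -0.74 in Newton for sucrose synthase and -0.54 in both for CYP86. The 5' probe set of sucrose synthase was dim in uninfested Molly (132 ± 30) and Newton (94.5 ± 27), near the range of the tag controls. Probe sets of both genes were themselves called as changed, so these ratios cannot tell RNA quality from a change of the transcript. For glucose-6-phosphate dehydrogenase the lines went opposite ways, by -0.3 in Molly and 0.13 in Newton (mean -0.09, exact permutation p = 0.43, BH-adjusted p = 0.43), and for ubiquitin by 0.12 and -0.02 (mean 0.05, exact permutation p = 0.24, BH-adjusted p = 0.3).

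How resistant Molly responded was asked first. At 6 h, XIP-I, an inhibitor of microbial xylanases, was 29.6-fold higher in infested sheaths, at 7550 ± 1300 against 262 ± 90 signal units (mean ± SD, n = 3; adjusted p = 5.1e-07). The zinc-finger gene WZF1 rose 10.9-fold, from 123 ± 36 to 1310 ± 130. GSTZ1, a glutathione transferase, rose 6.19-fold, from 89.2 ± 15 to 548 ± 53. That uninfested signal lay near the top of the range of the tag controls, so the sizes of GSTZ1 changes from it are uncertain. The alpha-tubulin gene TUBA rose 9.43-fold (adjusted p = 4.4e-05), the ribosomal protein gene RPS29 at least 6.18-fold from an uninfested signal within the range of the tag controls and the lipid transfer protein gene LTP3, in the dimmer of its 2 probe sets, 4.53-fold. The other, brighter TUBA probe set had a log2 change of -0.19 and missed the threshold (adjusted p = 0.051), as did the brighter of RPS29 at 0.816 (adjusted p = 0.075). The 6 named genes with the largest falls by the naming rule encode histones or a chromatin protein. The histone gene wcH2A-9 fell 4.34-fold, from 9990 ± 120 to 2310 ± 300 (n = 3, adjusted p = 2.2e-05). Falls of 4.02-fold for wcH2B-8, 2.76-fold for wcH2A-2 and 2.08-fold for the high mobility group gene Hmgb3 were also called.

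By group, 19 of 20 histone and chromatin probe sets, from 6 genes, fell in Molly at 6 h and 1 rose, and all 20 were called when adjusted over the list alone. Their median log2 change was -1.51 (camera adjusted p = 3.7e-10; adjusted p = 0.65 with an estimated correlation), while 18S rRNA signal on the same arrays changed by -1.48. With 18S rRNA signal as a covariate, added after seeing the data, the list was still called at the preset correlation in each infested group. The probe set of the list that rose was a dim one of wcH2A-3 (log2 change 0.665, adjusted p = 0.023), opposite to the other wcH2A-3 probe set. Of 6 cell wall, lipid transfer and glucosidase probe sets 4 rose and 0 fell (median 0.86, camera adjusted p = 0.032; adjusted p = 0.38 with an estimated correlation); LTP3 and Glc1 (log2 change 0.89) were among them and TaGlu1a had a log2 change of -0.16 (adjusted p = 0.16). Of 9 translation probe sets 6 fell and 1, RPS29, rose, with a median of -0.3 and a mean of 0.14 (camera adjusted p = 0.17). Of 12 tubulin and profilin probe sets 7 fell and 1 rose, with a median of -0.24 and a mean of 0.07 (camera adjusted p = 0.076). Among 12 peroxidase and detoxification probe sets, the 3 of GSTZ1 rose and 4 fell, lgul by 0.76 being one (median -0.16, mean 0.27, camera adjusted p = 0.99). PEAMT1, which makes phosphocholine by methylation, fell by 0.99 (adjusted p = 7e-04), the only called member among 7 methyl donor probe sets (camera adjusted p = 0.56); with 18S rRNA signal as a covariate its change was smaller and missed the threshold (-0.56, SE 0.25, adjusted p = 0.11, against -0.99, SE 0.21). WGA2, a wheat germ agglutinin, was not called (fitted log2 change -1.14, adjusted p = 0.27). The geometric mean of its infested arrays was within the range of the tag controls, and its uninfested arrays spanned 79.7 to 574.

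Carbohydrate genes went both ways in Molly at 6 h. Among 13 starch, fructan and sugar probe sets 2 rose and 3 fell (camera adjusted p for the list 0.94). A probe set of 6-FEH, a fructan exohydrolase, rose by at least 1.81 on the log2 scale, from an uninfested signal within the range of the tag controls. The other tested 6-FEH probe sets did not rise. GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, rose by 1.84. Its uninfested signal, 89.4 ± 28, lay near the top of the range of the tag controls, so the sizes of its changes from uninfested Molly are uncertain. Of 5 LEA, dehydrin and heat shock probe sets 3 rose, led by the dehydrin gene Rab15 at 1.74 and FKBP70 at 0.52 (camera adjusted p = 0.31). Of 19 photosynthesis probe sets 2 fell (camera adjusted p = 0.59). Of 5 inhibitor and serpin probe sets the 2 of XIP-I rose, while wci had a log2 change of 0.4 (adjusted p = 0.39; camera adjusted p for the list 0.13). In all, 13850 of 36707 probe sets changed, 6707 up and 7143 down, of which 3246 up and 1727 down by at least 2-fold. With arrays centred on their median, which moved the median log2 change from 0.021 to -0.109, the share that rose went from 48.4% to 35.4%. Without Molly 6 h replicate 1 or Molly uninfested replicate 3 the cell wall list missed the threshold (median 0.83 and 0.82, adjusted p = 0.052 and 0.053), as it did with 18S rRNA signal as a covariate, added after seeing the data (0.9, adjusted p = 0.069).

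At 12 h, where the uninfested Molly sheaths match the infested ones in time, the genes with the largest rises among those brighter than the median signal were again XIP-I, 35.0-fold to 9000 ± 2000 (n = 3, adjusted p = 5.1e-07), and WZF1, 11.3-fold. RPS29 rose at least 5.03-fold, its uninfested signal being within the range of the tag controls, GSTZ1 5.69-fold and LTP3 4.4-fold. The brighter RPS29 probe set was not called (log2 change 0.373, adjusted p = 0.46). Rab15 rose 3.48-fold, from 168 ± 50 to 571 ± 85. Histone genes fell again, wcH2B-8 by 3.41-fold and wcH2A-9 by 2.76-fold, and the list's median was -0.94 with 19 of 20 probe sets called as falls (camera adjusted p = 1.5e-05; adjusted p = 0.69 with an estimated correlation). The dim probe set of wcH2A-3 rose by 0.983 (adjusted p = 0.0016), and 18S rRNA signal changed by -1.75. PEAMT1 fell 2.09-fold, the purine synthesis gene AdSS 1.73-fold and the initiation factor gene eIF-2-beta by 0.65 on the log2 scale, 1 of 5 translation probe sets that fell against 1 that rose. The cell wall list had a median of 0.83, with 4 of 6 probe sets raised (camera adjusted p = 0.005; adjusted p = 0.38 with an estimated correlation), XTH among them at 0.89.

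Among 5 inhibitor and serpin probe sets at 12 h, the 2 of XIP-I rose, and 1 other was called from signals in or near the range of the tag controls (camera adjusted p for the list 0.061). GAPN rose by 1.33 (adjusted p = 0.0011), 1 of 2 called among 13 sugar metabolism probe sets. TUBA rose by 1.48 (adjusted p = 0.032) while its brighter probe set was not called (0.022, adjusted p = 0.86) and 4 other tubulin and profilin probe sets fell. The TUBA call was lost without Molly 12 h replicate 1 (1.34) or 2 (1.41) or uninfested replicate 2 (1.22) or 3 (1.54). In all 12514 probe sets changed in Molly at 12 h, 6024 up and 6490 down, 2779 and 1496 of them by at least 2-fold. The share that rose was 48.1%, or 35% with arrays centred on their median (median log2 change -0.015 and -0.133). With 18S rRNA signal as a covariate 6833 probe sets changed, and the calls of PEAMT1 (-0.55, SE 0.27, adjusted p = 0.18, against -1.06, SE 0.21) and Rab15 (1.88, SE 0.69, adjusted p = 0.066, against 1.8, SE 0.46) were lost, the first with a smaller change and the other with a wider SE alone.

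At 24 h in Molly, XIP-I was 12.2-fold higher with a wide spread between arrays (3850 ± 3100 against 262 ± 90, n = 3, adjusted p = 4.3e-05). TUBA rose 10.3-fold, WZF1 5.03-fold and LTP3 3.15-fold. GAPN rose 6.84-fold, from an uninfested signal near the top of the range of the tag controls (89.4 ± 28). CAT1, a catalase, rose 2.96-fold, and with GSTZ1 at a log2 change of 1.78 made 4 rises and 4 falls among 12 detoxification probe sets (camera adjusted p = 0.88). TaPrx1 fell 1.7-fold, from 8350 ± 600 to 4930 ± 750 (n = 3, adjusted p = 0.0012). RPL9, a ribosomal protein gene, fell 1.56-fold, Hmgb3 1.53-fold and AGA.1 1.51-fold. The brighter TUBA probe set (log2 change -0.071, adjusted p = 0.56) and the dimmer AGA.1 one (0.183, adjusted p = 0.73) were not called. Of 20 histone and chromatin probe sets 3 fell and 0 rose, with a median of -0.48 (camera adjusted p = 0.0075; adjusted p = 0.79 with an estimated correlation), and 18S rRNA signal changed by -0.97. The cell wall list had a median of 0.6 with 4 of 6 probe sets raised (camera adjusted p = 0.032; adjusted p = 0.38 with an estimated correlation). Of 4 seed storage and anther probe sets 1, ALP, fell by 0.3 (adjusted p = 0.0021).

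In all 8782 probe sets changed in Molly at 24 h, 4351 up and 4431 down, and at least 2-fold changes were 2083 up and 504 down. The share that rose was 49.5%, or 33.2% with arrays centred on their median (median log2 change -0.018 and -0.129). The histone list's call was lost without Molly 24 h replicate 1 (median -0.22, adjusted p = 0.17) and under quantile normalization (-0.39, adjusted p = 0.062). The cell wall list's call was lost without that array (0.52, adjusted p = 0.052), without Molly uninfested replicate 3 (0.54, adjusted p = 0.061) and with 18S rRNA signal as a covariate (0.63, adjusted p = 0.069).

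**Figure D2:**
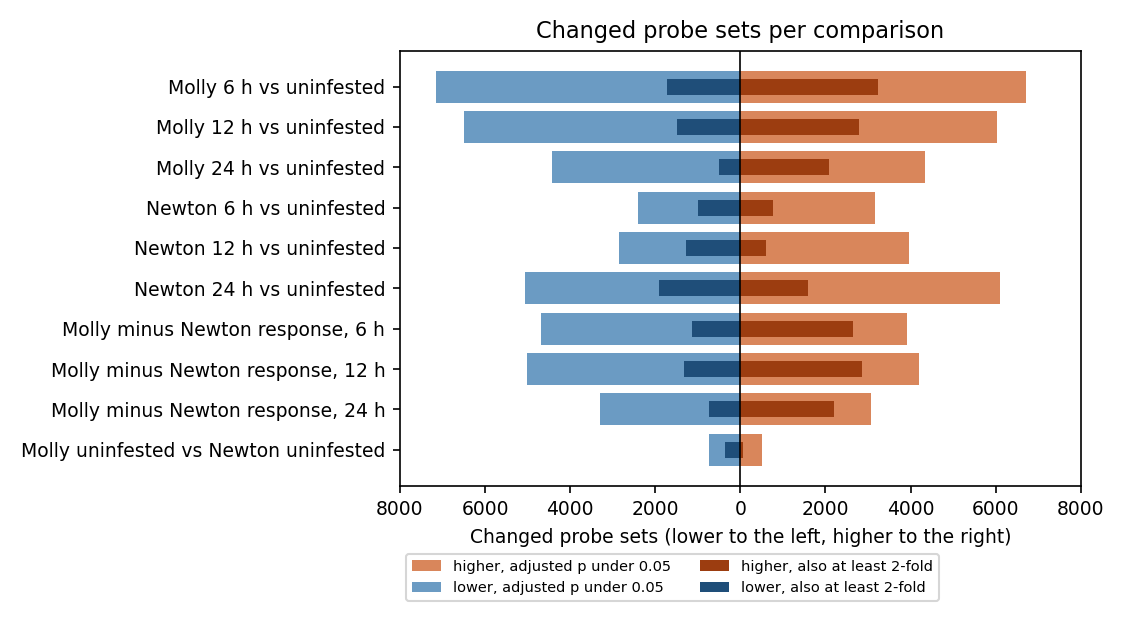
Number of probe sets that rose (above 0) or fell (below 0) in each comparison, with wide bars for an adjusted p under 0.05 and narrow dark bars for those that also changed at least 2-fold. Molly went from 13850 changed probe sets at 6 h to 8782 at 24 h, and Newton from 5570 to 11167.

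How susceptible Newton responded was asked in the same way. At 6 h, FKBP70, a peptidyl-prolyl isomerase that binds FK506, rose 1.85-fold, from 6700 ± 240 to 12400 ± 570 (n = 3, adjusted p = 0.00016). TUBA rose 3.99-fold, from 117 ± 21 to 471 ± 120. The brighter LTP3 probe set fell 2.1-fold, from 9580 ± 570 to 4640 ± 1000, and Hmgb3 1.75-fold. COMT1, a methyltransferase of lignin precursors, fell 1.34-fold, the only called member of 7 methyl donor probe sets (camera adjusted p = 0.076). The beta-amylase gene BMY1 fell 1.61-fold, lgul 1.61-fold, and the Calvin cycle gene PRK 1.53-fold, 1 of 2 called falls among 19 photosynthesis probe sets (camera adjusted p = 0.46). The other probe sets of TUBA (log2 change -0.08, adjusted p = 0.54), LTP3 (-0.612, adjusted p = 0.18) and lgul (-0.409, adjusted p = 0.15) were not called, nor was the XIP-I probe set that rose in Molly (0.39, adjusted p = 0.69).

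The histone and chromatin list had a median of -0.52 in Newton at 6 h, with 2 of 20 probe sets called, both of Hmgb3 (camera adjusted p = 1.5e-05; adjusted p = 0.69 with an estimated correlation). It was -0.28 without Newton 6 h replicate 3, and 18S rRNA signal changed by -2.07. In all 5570 probe sets changed, 3172 up (56.9%, or 48.9% with arrays centred on their median) and 2398 down, with 766 and 1006 by at least 2-fold; with 18S rRNA signal as a covariate 1865 did. With that covariate lgul, PRK and COMT1 were no longer called (adjusted p = 0.18, 0.35 and 0.31). Their log2 changes were -0.76 (SE 0.32), -0.53 (SE 0.3) and -0.26 (SE 0.14) against -0.69 (SE 0.19), -0.61 (SE 0.18) and -0.42 (SE 0.09) without it, so the wider SE rather than a smaller change ended the call of lgul. Single arrays decided other calls: TUBA without Newton 6 h replicate 3 (1.81, adjusted p = 0.051), lgul without Newton 6 h replicate 1 (-0.58) or uninfested replicate 2 (-0.62), PRK without Newton 6 h replicate 1 (-0.39) or 2 (-0.62) or uninfested replicate 1 (-0.63) or 2 (-0.54), and BMY1 without Newton 6 h replicate 2 (-0.52) or 3 (-0.71) or uninfested replicate 1 (-0.67), 2 (-0.71) or 3 (-0.69).

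At 12 h in Newton, with matched sampling times, BMY1 fell 2.26-fold, from 740 ± 17 to 329 ± 46 (n = 3, adjusted p = 0.00075). The same LTP3 probe set fell 1.76-fold and COMT1 1.51-fold, from 16700 ± 140 to 11100 ± 1900. TUBA was 4.08-fold higher with a wide spread (701 ± 670, n = 3, adjusted p = 0.009), and Glc1 rose 1.46-fold. FKBP70 rose by 0.54 on the log2 scale and Rab15 by at least 1.52, from an uninfested signal within the range of the tag controls. The photosystem gene PsbP fell 1.46-fold, while 2 probe sets in that list rose. The other probe sets of TUBA (log2 change -0.05, adjusted p = 0.71), LTP3 (-0.189, adjusted p = 0.72) and PsbP (-0.221, adjusted p = 0.17) were not called. In the sugar list 1 probe set, AGP-S, rose by 0.2 and 4 fell. Of 12 tubulin and profilin probe sets 4 fell, Tubb4 among them by 0.36 (camera adjusted p = 0.26). No inhibitor, translation or gibberellin 20-oxidase probe set was called, and the XIP-I probe set that rose in Molly had a log2 change of 1.28 (adjusted p = 0.098).

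The histone list had a median of -0.52 in Newton at 12 h, with 2 of 20 probe sets, both of wcH2B-6, called over all probe sets and 11 called when adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.69 with an estimated correlation). It ranged from -0.79 without Newton 12 h replicate 3 to -0.25 without replicate 2, and 18S rRNA signal changed by -1.54. The methyl donor list had a median of -0.21 with COMT1 its 1 called member (camera adjusted p = 0.018; adjusted p = 0.69 with an estimated correlation), and its call was lost without Newton 12 h replicate 1 (-0.19, adjusted p = 0.051) or 3 (-0.09, adjusted p = 0.12). In all 6820 probe sets changed, 3973 up (58.3%, or 54.2% with arrays centred on their median) and 2847 down, with 600 and 1285 by at least 2-fold. The count was 4496 without Newton 12 h replicate 2, 4012 with only the arrays of the compared groups and 3540 with 18S rRNA signal as a covariate. Without Newton 12 h replicate 2 the calls of TUBA (1.22), Glc1 (0.35), PsbP (-0.38), Tubb4 (-0.27), AGP-S (0.23), wcH2B-6 (-0.44), Rab15 (0.96) and FKBP70 (0.34) were lost. Those of PsbP (-0.49) and Tubb4 (-0.34) were lost without Newton uninfested replicate 2 and that of Glc1 (0.46) without replicate 3. The calls of AGP-S (0.19 to 0.21) and wcH2B-6 (-0.57 to -0.62) were lost without any 1 of the uninfested arrays, and also without Newton 12 h replicate 3 (0.14) and replicate 1 (-0.55) respectively.

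At 24 h in Newton, TUBA rose 13.3-fold, from 117 ± 21 to 1590 ± 530 (n = 3, adjusted p = 2.1e-05), and Rab15 at least 4.07-fold from an uninfested signal within the range of the tag controls. CAT1 rose 2.54-fold, FKBP70 2.28-fold to 15300 ± 620, the xyloglucan endotransglucosylase gene XTH 2.13-fold and Glc1 2.04-fold. The histone genes wcH2A-9 and wcH2B-8 fell 3.39-fold and 2.84-fold, wcH2A-2 2.8-fold, wcH2A-3 2.64-fold and Hmgb3 2.44-fold. The brighter TUBA probe set (log2 change 0.154, adjusted p = 0.13) and the dim one of wcH2A-3 (0.269, adjusted p = 0.4) were not called. BMY1 fell 2.46-fold to 305 ± 69. RPL9 fell by 0.6 on the log2 scale, the 1 fall against 3 rises in 9 translation probe sets (camera adjusted p = 0.56). Of the detoxification probe sets 2 rose and 2 fell (camera adjusted p for the list 0.36). Those that rose were CAT1 and 1 of GSTZ1 (at least 1.36), while the other GSTZ1 probe sets did not rise. TaPrx1 had a log2 change of -0.28 (adjusted p = 0.2). SAHH, which recycles the by-product of methyl transfer, rose by 0.34 (adjusted p = 0.0011).

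Of 20 histone and chromatin probe sets, 19 fell and 0 rose in Newton at 24 h, with a median of -1.26 (camera adjusted p = 2.8e-11; adjusted p = 0.61 with an estimated correlation), and 18S rRNA signal changed by -2.1. Of 5 LEA, dehydrin and heat shock probe sets 3 rose and 0 fell (camera adjusted p = 0.21). In the cell wall list XTH and Glc1 rose and 2 probe sets fell, one being the brighter LTP3 probe set (-1.06; camera adjusted p = 0.99). Among all probe sets 11167 changed, 6106 up (54.7%, or 52.3% with arrays centred on their median) and 5061 down, with 1591 and 1915 by at least 2-fold. With 18S rRNA signal as a covariate 5685 changed, and the calls of Rab15 (1.96, SE 0.67, adjusted p = 0.055, against 2.03, SE 0.4) and wcH2B-8 (-1.47, SE 0.58, adjusted p = 0.096, against -1.51, SE 0.35) were lost, mainly through wider SE.

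**Figure D3:**
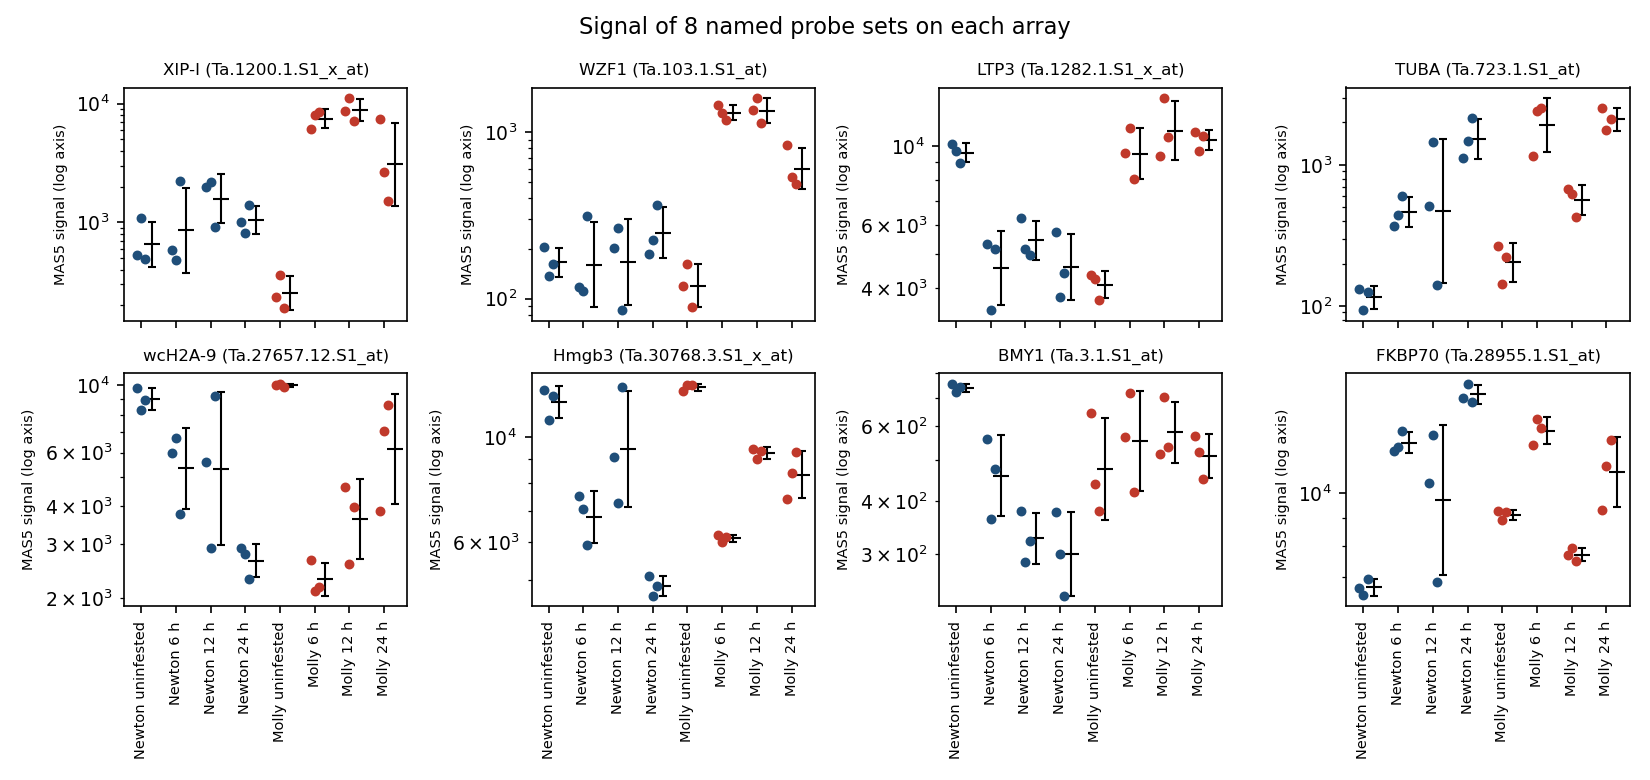
Signal of 8 named probe sets on each array (dots, log axis), with a dash at the geometric mean and bars of 1 SD on the log2 scale, Newton in blue and Molly in red, by sampling time and with the uninfested groups. XIP-I averaged 262 in uninfested Molly and 7550 at 6 h, and wcH2A-9 averaged 9990 and 2310.

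Whether the responses of the lines differed was tested directly. At 6 h the response of Molly exceeded that of Newton by 4.5 on the log2 scale for XIP-I (SE 0.74, adjusted p = 0.00023), by 3.49 for WZF1 and by 2.79 for the dimmer LTP3 probe set. GAPN differed by 2.7 and GSTZ1 by 2.49 in the same direction. Since the uninfested Molly signal of GAPN lay near the top of the range of the tag controls, the sizes of its differences are uncertain at each time. Histone responses were lower in Molly than in Newton, with differences of -1.44 for wcH2B-8 (adjusted p = 0.037), -1.37 for wcH2A-9 (adjusted p = 0.032) and -1.12 for wcH2A-2 (adjusted p = 0.034). Of 20 histone and chromatin probe sets 15 were lower in Molly's response and 0 higher (median -1.01, camera adjusted p = 0.00014; adjusted p = 0.71 with an estimated correlation). The cell wall list differed by a median of 0.43 (camera adjusted p = 0.032; adjusted p = 0.38 with an estimated correlation), its 2 called probe sets both being of LTP3. COMT1 differed by 0.41 (adjusted p = 0.019), and 18S rRNA signal had changed by -1.48 in Molly and -2.07 in Newton.

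In all 8590 probe sets differed in response at 6 h, 3912 more positive in Molly (45.5%, or 35.1% with arrays centred on their median) and 4678 less, with 2640 and 1136 by at least 2-fold. Of 100 splits of the arrays 7 gave as many, the real one included. The cell wall list's call was lost without Molly uninfested replicate 3 (0.39, adjusted p = 0.052). The calls of the histone genes were lost for wcH2B-8, wcH2A-9 and wcH2A-2 without Newton 6 h replicate 1 (-1.41, -1.28 and -0.94) or 2 (-1.21, -1.2 and -0.97), Molly 6 h replicate 2 (-1.38, -1.3 and -1.1) or 3 (-1.44, -1.33 and -1.08), Newton uninfested replicate 2 (-1.35, -1.31 and -1.06) and Molly uninfested replicate 1 (-1.4, -1.36 and -1.13) or 3 (-1.47, -1.38 and -1.01). They were lost as well for wcH2B-8 and wcH2A-9 without Newton uninfested replicate 3 (-1.43 and -1.36) or Molly uninfested replicate 2 (-1.46 and -1.36), and for wcH2A-2 without Newton uninfested replicate 1 (-1.12).

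At 12 h the responses differed by 3.85 for XIP-I (SE 0.74, adjusted p = 0.00068), 3.49 for WZF1, 2.32 for the dimmer LTP3 probe set and 2.41 for GAPN, all more positive in Molly. Of 5 inhibitor and serpin probe sets 3 were called in that direction, the 2 of XIP-I and a dim one in or near the range of the tag controls (camera adjusted p = 0.076). Responses were less positive in Molly for FKBP70 (-0.78), AdSS (-0.76) and eIF-2-beta (-0.56, adjusted p = 0.00081). COMT1 differed by 0.51 in the other direction (adjusted p = 0.0046). In the histone list 1 probe set, the dim one of wcH2A-3, was called with a difference of 1.07 (0.86 and not called without Newton uninfested replicate 2), and the list missed the threshold (median -0.45, camera adjusted p = 0.33). The cell wall list differed by a median of 0.39 (camera adjusted p = 0.017; adjusted p = 0.38 with an estimated correlation), both called probe sets being of LTP3. In all 9201 probe sets differed, 4190 more positive in Molly (45.5%, or 35.5% with arrays centred on their median) and 5011 less, with 2867 and 1323 by at least 2-fold.

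At 24 h the differences were 2.94 for XIP-I (SE 0.74, adjusted p = 0.0087), 2.4 for the brighter LTP3 probe set (adjusted p = 1.1e-06) and 2.13 for GAPN. The brighter LTP3 probe set stood at 10400 ± 670 in infested and 4110 ± 350 in uninfested Molly (n = 3), while it fell in Newton. Responses were less positive in Molly for FKBP70 (-0.92), PEAMT1 (-0.88, adjusted p = 0.045) and the beta-tubulin gene Tubb5 (-0.45). For histones the sign was opposite to that at 6 h: the median difference was 0.73, with 2 of 20 probe sets more positive in Molly, both of Hmgb3 (camera adjusted p = 2.8e-05; adjusted p = 0.7 with an estimated correlation). In all 6367 probe sets differed, 3070 more positive in Molly (48.2%, or 35.7% with arrays centred on their median) and 3297 less, with 2198 and 728 by at least 2-fold. The PEAMT1 call was lost without Newton 24 h replicate 1 (-0.84) or 2 (-0.82), Molly 24 h replicate 1 (-0.65) or 2 (-0.88), Newton uninfested replicate 1 (-0.88) or 2 (-0.81), or Molly uninfested replicate 2 (-0.82) or 3 (-0.83).

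**Figure D4:**
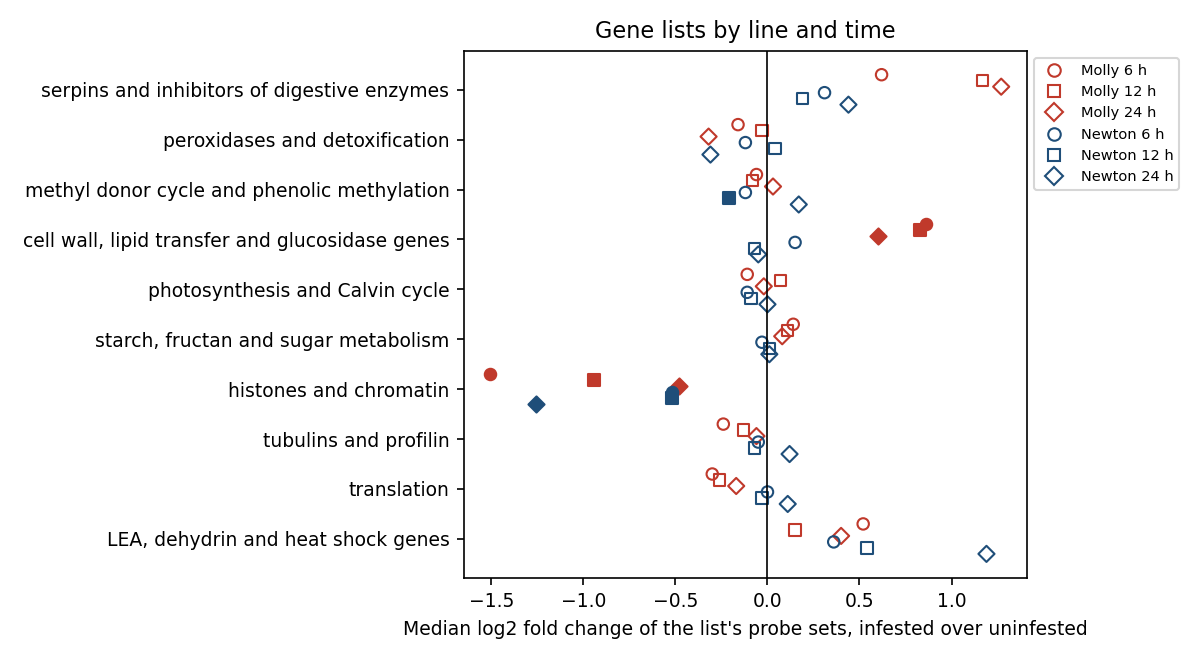
Median log2 change of each of the 10 tested gene lists in each infested group, against the uninfested group of its line. Points are filled where camera with its preset correlation gave an adjusted p under 0.05 and open otherwise. The histone list lies between -1.51 (Molly at 6 h) and -0.48 (Molly at 24 h) in the infested groups; the filled calls were lost with an estimated correlation.

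How far the lines responded alike was measured across probe sets, which are not independent replicates. The log2 changes of Molly and Newton correlated at r = 0.336 at 6 h (rho 0.303), 0.185 at 12 h (rho 0.182) and 0.328 at 24 h (rho 0.285). At 24 h, 1660 probe sets rose in both lines and 1575 fell in both, against 724 and 611 if the calls of the lines were independent. At 6 h these were 1402 and 877 against 580 and 467, and at 12 h 1148 and 733 against 652 and 503. Opposite calls at 12 h were 533 up in Molly and down in Newton and 529 the other way, against 467 and 702. Without Newton 6 h replicate 3 the correlation at 6 h was 0.221 and the same-direction calls fell from 2279 to 1473, and without Newton uninfested replicate 1 to 1502. Those at 12 h went from 1881 to 1180 without Newton 12 h replicate 2 and to 1229 without Newton uninfested replicate 1. With no filter on dim probe sets the correlations were 0.195, 0.0912 and 0.184.

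Without larvae, the lines differed in few named genes. The brighter LTP3 probe set was 2.34-fold lower in Molly, at 4110 ± 350 against 9580 ± 570 (n = 3, adjusted p = 0.00063), while the dimmer was not called (log2 difference -0.291, adjusted p = 0.68), and the beta-tubulin gene Tubb4 was 1.41-fold lower (adjusted p = 0.008). GAPN was lower by -1.29 on the log2 scale (adjusted p = 0.016), the 1 called member of 13 sugar probe sets. Its Molly signal, 89.4 ± 28, lay near the top of the range of the tag controls, so that size is uncertain. No histone, photosynthesis, translation or detoxification probe set was called, wheat germ agglutinin WGA2 had a log2 difference of 0.01, and the lowest camera adjusted p of a list was 0.24. In all 1247 probe sets differed, 503 higher in Molly (40.3%, or 50.3% with arrays centred on their median) and 744 lower, with 64 and 370 by at least 2-fold. The count was 340 and 513 without Newton uninfested replicates 2 and 1, 364 and 705 without Molly uninfested replicates 3 and 2, and 2693 with only the arrays of these groups. The Tubb4 call was lost without Molly uninfested replicate 3 (-0.43), and the GAPN call without Newton uninfested replicate 1 (-1.29) or 2 (-1.2) or Molly uninfested replicate 2 (-1.28) or 3 (-1.07).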

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

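The tests of the histone pattern, of 18S rRNA and of sampling time at 6 and 24 h, and the use of the correlation at 12 h and of each fit's own bound, were chosen only after the result was seen, and the bounds of the growing-tissue and 18S rRNA tests were revised with their values known, which moved the 18S rRNA test from counting against the explanation to undecided.

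The pattern weighed first was lower histone and chromatin signal in infested sheaths of both lines. Between-array scaling is argued against, since the list median in Molly at 6 h was -1.64 and -1.43 under median centring and quantile normalization, against -1.51 as deposited. Cross-hybridising probe sets of 1 gene are argued against too, since the 6 genes with a called fall included H2A and H2B genes and Hmgb3. Cross-hybridisation between genes of 1 histone type was not tested, so the 6 may not be separate readings. A smaller share of growing tissue in the sampled piece may contribute and cannot be told apart: tubulin and translation genes had medians of -0.24 and -0.3 in Molly at 6 h, neither at or above 0 nor as low as the bound of -0.5 set from the histone median. In Newton at 24 h these medians were 0.12 and 0.11 while that of histones was -1.26, which speaks against it there, but both lists held called rises and falls (3 and 1 in each), so it is left open, as is an effect of infestation on these genes.

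The next pattern was the set of probe sets changed in the same direction in both lines. Sampling time as the whole cause predicted that at 12 h, where times match, shared calls would stay under a bound set from 6 and 24 h. They numbered 1881, over the bound of 1139.5. Of 24 fits with 1 array left out, only that without Newton 12 h replicate 2 was under its own bound (1180 against 1326.5). That count alone cannot decide, since independent calls would give 652 shared rises and 503 shared falls, together already over the bound. Sampling time as the whole cause is argued against by the excess over these, with 1148 shared rises and 733 shared falls. Responses also correlated at 12 h, at r = 0.185 (0.129 to 0.231 with 1 array left out). Whether it adds to the sharing at 6 and 24 h cannot be told apart, since the lower of those counts exceeded that at 12 h by 398, with a range of -579 to 1473 with 1 array left out. Time-dependent expression shared by the lines may account for part of the sharing. The change of 12 h against the mean of 6 and 24 h correlated between the lines across probe sets at r = 0.436, as this predicts. With 1 array left out r was 0.388 to 0.479. That change was taken from infested arrays alone, so a time course of the response to larvae shared by the lines would give the same. An RNA or labelling difference of the uninfested arrays cannot be told apart from infestation: within groups, 18S rRNA signal and the shared 12 h score correlated over 24 arrays at r = 0.049 (interval -0.44 to 0.52; rho -0.013; permutation p = 0.88 and 0.97; -0.0416 without the 2 farthest arrays), and a response shared by both lines stays open.

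The last pattern was Newton 6 h replicate 3, which lay nearer to infested Molly than the other Newton 6 h arrays. Molly RNA or tissue mixed into the sample cannot be told apart. Over 19 probe sets that mark the lines the array lay at 0.12 of the way to Molly. The other 8 infested Newton arrays ranged from -0.11 to 0.14 (mean 0.031, SD 0.076). Over 2399 probe sets that responded in Molly at 6 h and were not called in Newton at 12 or 24 h, it lay at 0.29. A mixture was taken to move the array by at least 0.14 above that mean, which the spread does not separate from no mixture. Positions were also taken on the log2 scale, where a mixture moves probe sets higher and lower in Molly by unequal amounts. A later stage of the Newton response is consistent with its position of 0.785 on the axis from uninfested Newton to Newton at 24 h, against 0.617 and 0.626 for the other replicates.

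Counts of probe sets whose response differed between the lines were flagged at each time, whatever their size. At 6 h 8590 probe sets differed, and 7 of 100 splits of the arrays gave as many, the real one included, with 10348 in the highest other. At 12 h 9201 differed, with 1 of 100 splits and 8622 in the highest other, and at 24 h 6367 differed, with 3 of 100 and 12268. The other splits that reached the real count, 6 at 6 h and 2 at 24 h, all kept the infested and uninfested arrays of a line whole and so carry that line's change with infestation, and splits that mixed both lines gave at most 1. That structure of the samples sets the share, which therefore does not settle whether chance is excluded for any of these 3 counts. For the comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 13850 and 1 for Molly at 6 h, 12514 and 1 at 12 h and 8782 and 2 at 24 h. For Newton they were 5570 and 4, 6820 and 2, and 11167 and 2, and for the uninfested lines 1247 and 5.

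Gene lists whose responses differed between lines were cell wall genes at 6 h (0.43) and 12 h (0.39) and histones at 6 h (-1.01) and 24 h (0.73), as median log2 differences of Molly minus Newton. With an estimated correlation these calls were lost (adjusted p = 0.38, 0.38, 0.71 and 0.7). Named genes at 6 h were XIP-I (4.5), WZF1 (3.49), LTP3 (2.79), wcH2B-8 (-1.44), wcH2A-9 (-1.37) and wcH2A-2 (-1.12). At 12 h they were XIP-I (3.85), WZF1 (3.49), LTP3 (2.32), FKBP70 (-0.78), AdSS (-0.76) and eIF-2-beta (-0.56). At 24 h they were XIP-I (2.94), LTP3 (2.4), GAPN (2.13), FKBP70 (-0.92), PEAMT1 (-0.88) and Tubb5 (-0.45).

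Changes from the uninfested arrays also appeared in wheat control probe sets, which were left out of the 36707 tested probe sets. Their p-values were adjusted over these controls alone, in all infested groups together. Control probe sets of the 3' and 5' ends of CYP86 had entered the RNA quality ratios. The middle probe set of sucrose synthase rose by 1.9, 1.42 and 1.46 on the log2 scale in Molly at 6, 12 and 24 h and by 1.1, 0.9 and 1.79 in Newton. That of glucose-6-phosphate dehydrogenase rose by 0.8 and 0.74 in Molly at 6 and 12 h and by 0.63 in Newton at 24 h, and that of ubiquitin by 0.25 in Molly at 12 h, while it fell by 0.23 in Newton at 12 h. Of 2 middle GAPDH probe sets 1 was called in Newton at 12 and 24 h (fitted log2 changes 2.4 and 2.1), but its mean signals of 88 and 68.9 lay near or within the range of the tag controls, so no size is given, and the other was not called (0.27 and 0.04, adjusted p = 0.72 and 0.97). Falls occurred too, since the 3' probe set of CYP86 fell by 0.65, 0.71 and 0.82 in Newton at 6, 12 and 24 h (n = 3, limma adjusted p = 0.00086, 0.00044 and 0.00021) and the middle one fell by 0.62 at 24 h (adjusted p = 0.0099), while in Molly the 5' one rose by 0.56 and 0.61 at 6 and 12 h (adjusted p = 0.04 and 0.026).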

How the results depend on the processing

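The fit with 18S rRNA signal as a covariate was chosen only after the result was seen. Of the 164 named gene results past the threshold 0 changed direction, while the balance of rises and falls did turn under the settings named next. Without a filter the share that rose was 51.1%, 50.3% and 52.7% in Molly at 6, 12 and 24 h and 51% for the difference at 24 h. It was 51.3% and 52.6% in Molly at 12 and 24 h with the 18S rRNA covariate, 50.2% and 50.7% in Molly at 24 h with the replicate block and without the trend, and 52.1%, 48.2% and 48.7% in Molly at 24 h and Newton at 6 and 12 h with only the compared groups. Median centring gave 48.9% in Newton at 6 h and 50.3% for the uninfested lines. A change of at least 2-fold turned it too: 65.3%, 65% and 80.5% in Molly, 43.2%, 31.8% and 45.4% in Newton and 69.9%, 68.4% and 75.1% for the differences. For the values below the cause was not tested unless stated. A change of at least 2-fold, a stricter rule by construction, left 4973, 4275 and 2587 probe sets in Molly at 6, 12 and 24 h, 1772, 1885 and 3506 in Newton, 3776, 4190 and 2926 for the differences, and 434 for the uninfested lines. With 18S rRNA signal as a covariate the counts were 6833 for Molly at 12 h and 1865, 3540 and 5685 for Newton, the other 6 staying within 1.5 times; the cell wall list missed the threshold in Molly at 6 h (0.9) and 24 h (0.63), and the methyl donor list in Newton at 12 h (-0.2). With only the arrays of the compared groups the counts were 4012 for Newton at 12 h and 2693 for the uninfested lines, and the methyl donor list missed the threshold (-0.21). Under quantile normalization so did that list (-0.22) and the histones in Molly at 24 h (-0.39). With no filter the correlations between lines were 0.195, 0.0912 and 0.184 and the called list shifts went from 14 to 24; with the lowest 60% left out the correlation at 24 h was 0.385. Ranges with 1 replicate left out were 4496 to 7790 for Newton at 12 h, 340 to 881 for the uninfested lines and 0.221 to 0.383 for the correlation at 6 h. For lists they were 0.82 to 0.91 (cell wall, Molly 6 h), 0.52 to 0.67 (Molly 24 h) and 0.31 to 0.59 (difference at 6 h), -0.68 to -0.22 (histones, Molly 24 h) and -0.36 to -0.09 (methyl donor, Newton 12 h). Median centring, the pseudocount, the variance prior without trend and the replicate block kept all 10 counts within 1.5 times, and the replicate numbers do not pair the samples, since 84 pairs of arrays with equal numbers had a median r of -0.013 after group means were removed. Of those named gene results 105 were called under every alternative and 59 lost the call under 1 or more. Signals in the range of the tag controls, up to 85, limit what can be said of dim probe sets.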

Other observations

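The fit with 18S rRNA signal as a covariate was chosen only after the result was seen.

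Of 3 tested gibberellin 20-oxidases, enzymes of gibberellin synthesis, 2 rose in infested Molly from uninfested signals within the range of the tag controls. GA20ox1d rose by at least 1.71, 1.27 and 1.22 on the log2 scale at 6, 12 and 24 h (n = 3, limma adjusted p = 6.6e-05, 0.00026 and 0.00058). GA20ox1b rose by at least 1.16 and 0.81 at 6 and 12 h (adjusted p = 0.00055 and 0.0037). With 18S rRNA signal as a covariate GA20ox1b was not called at 12 h, at a fitted log2 change of 1.37 (SE 0.58, adjusted p = 0.11) against 1.54 (SE 0.39) without it, mainly through the wider SE. Its call at 24 h (fitted log2 change 1.18, SE 0.39, adjusted p = 0.032) was lost with that covariate (1.08, SE 0.46, adjusted p = 0.12) and without Molly 24 h replicate 1 (1.07) or 2 (1.12) or Molly uninfested replicate 1 (0.69). GA20ox1a was not called (adjusted p = 0.92, 0.96 and 0.36). In Newton 0 of the 3 were called, with group signals within the range of the tag controls, so the size of a difference between the lines is not given.

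Defence proteins of the thionin, PR5 and agglutinin list had 1 tested probe set, of WGA2, which was not called in any infested group. Its fitted log2 changes were -1.14, -1.64 and 0.07 in Molly at 6, 12 and 24 h (adjusted p = 0.27, 0.12 and 0.96). In Newton they were -1.72, -1.81 and 0.49 (adjusted p = 0.15, 0.12 and 0.69). At 6 and 12 h the infested groups of both lines had geometric means within the range of the tag controls, so these sizes are uncertain. The uninfested arrays spanned 79.7 to 574 in Molly and 87.9 to 434 in Newton. PR5 was below the filter and was not tested. Its signal was 134 ± 65 and 114 ± 60 in infested Molly at 6 and 12 h (mean ± SD, n = 3), with single arrays from 59 to 208. At 24 h it was 49 ± 39, with single arrays from 4.36 to 77.5, all within the range of the tag controls. Uninfested Molly and Newton arrays reached at most 7.18, and infested Newton groups averaged 2.41 to 3.08. Thionin signals were within the range of the tag controls on each array.

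Sucrose synthase, an enzyme of sugar use, was read by 3 control probe sets, each of which rose in each infested group. The middle one went from 1280 ± 170 to 4870 ± 1300 in Molly at 6 h and from 981 ± 120 to 3390 ± 460 in Newton at 24 h (mean ± SD, n = 3). Their sizes differed, with log2 changes of 1.05, 1.79 and 1.97 for the 3', middle and 5' ones in Newton at 24 h. The 3' to 5' ratio of this gene, read as RNA quality, also differed with infestation (mean -0.53). For glucose-6-phosphate dehydrogenase the 3 probe sets rose in Molly at 6 and 12 h and 2 of 3 rose in Newton at 24 h; 0 were called in Molly at 24 h or in Newton at 6 and 12 h, where the 5' one had a log2 change of -0.14 at 12 h (adjusted p = 0.58).

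A hypothesis was that the response recedes in Molly and grows in Newton between 6 and 24 h. Over probe sets changed at 12 h, the change from 6 to 24 h, signed by the direction at 12 h and taken from infested arrays alone, had a median of -0.273 in Molly (below 0 in 9 of 9 pairs of arrays) and of 0.084 in Newton (above 0 in 8 of 9 pairs). The signs are those the hypothesis predicts, but the Newton value did not hold in every pair, so the hypothesis stayed undecided. Plant age and time of day also differ between those times.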
